A study of Mus musculus with 27 samples.

How the data were processed

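RNA from mouse kidney and a universal mouse reference RNA, a commercial pool of RNA from cell lines, were labelled and hybridised to a mouse 3′ expression array with 45101 probe sets. The labels name 3 labelling procedures, OneRA, TwoRA and RS. What the names stand for is not given in the sources used here, so the names are used as they are. The labels give 10 µg of input for OneRA and 10 ng for TwoRA. Both RNAs were labelled by RS from 10 ng, and kidney RNA also from 100, 30 and 3 ng. The 27 arrays fall into 9 groups of 3. The labels name 1 supplier for each RNA and no animals, and do not say what the 3 arrays of a group share. The p-values therefore measure only the spread between these arrays, which may be technical.

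The deposited values, per the file headers, are a signal intensity per probe set on a linear scale and a detection p-value per probe set. The authors scaled the signals before deposit: the mean of the signals between the 2nd and 98th percentile lay between 499.84 and 499.888 on every array. The software and its version are not given in the sources used here. The value table and the per-array tables were checked against each other, and 0 signals differed. A probe set counted as present on an array when its detection p-value was below 0.05. The files hold no probe-level intensities, so nothing before the probe-set signals could be recomputed. No depth is recorded for arrays, and the 3 arrays per group limit the precision.

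Each array was scaled to a trimmed mean of 500, which changed almost nothing, and the signals were transformed as log2 of the signal plus 32. The 64 control probe sets were left out of the fit, as were probe sets with a mean signal below 100 over the 27 arrays, leaving 28914. A mean per group was fitted to all arrays with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation and a mean-variance trend (18 residual and 9.97 prior degrees of freedom). All limma tests were two-sided, and p-values were adjusted by the method of Benjamini and Hochberg over the 28914 probe sets of a contrast. A probe set was called when its adjusted p was below 0.05 and its difference at least 2-fold. The words rose, fell, higher and lower are used of single genes that met both. The 15 contrasts were kidney minus reference by each procedure, each pair of procedures within each RNA, the 3 differences between procedures of the kidney minus reference difference (called interactions), and RS at 30, 10 and 3 ng minus 100 ng.

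Symbols came from the platform annotation, updated through gene identifiers for 34754 probe sets. In all, 34958 probe sets carried 1 symbol, 932 several and 9211 none, with 18194 distinct symbols. Values of named genes are for the probe set with the highest mean signal. Named genes were chosen by a rule fixed beforehand, as the called genes with the highest and lowest log2 difference whose groups do not overlap. The rule takes 10 each way for kidney minus reference by OneRA, RS minus TwoRA in kidney and RS 3 ng minus 100 ng, and 5 each way for TwoRA minus OneRA and RS minus OneRA in kidney and for each interaction. It adds up to 4 members of each gene list with the largest absolute difference in the contrast described, and any gene named outside it is pointed out as chosen after its values were seen. Folds are on the log2 scale with 32 added and so understate genes of low signal. Where a gene was present on none of the dimmer group's arrays, the fold is a lower bound, computed against the higher, on each array, of its own signal and the lowest signal called present, and is written as at least. No fold is given when neither group had the gene present. Interactions have no such bound and are given on the log2 scale.

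Gene lists were fixed beforehand, 25 in all. They cover markers of proximal tubule, loop of Henle, distal tubule, collecting duct, podocyte, renal endothelium and renin cells, erythroid cells, hepatocyte, leukocyte, melanocyte, skeletal muscle, germ cell and gonad, fibroblast and extracellular matrix, simple epithelium, embryonic genes and adipocyte. They also cover genes of the cell cycle, immediate early and stress response, heat shock, cytosolic ribosomal proteins, oxidative phosphorylation, replication-dependent histones, proteasome, translation initiation factors and mitochondrially encoded genes. The last had 0 genes measured, so 24 were tested. A list was tested over 13678 genes with camera in limma, with a preset correlation of 0.01 between genes and again with an estimated correlation, and p-values were adjusted over the 24 lists of a contrast. Members were also counted with p-values adjusted over the list alone.

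The ratio of 3′ to 5′ signal was taken on the log2 scale for 4 control transcripts, Gapdh, beta-actin, transferrin receptor and pyruvate carboxylase, and averaged. Groups were compared by exact two-sided permutation tests. Within an RNA the 20 labelings of 6 arrays allow no p below 0.1. Permuting within both RNAs gives 400 labelings and a smallest p of 0.005. Agreement between procedures was described by correlations across probe sets, which are not independent replicates, so no p is given. Contrasts that share arrays were not correlated with each other.

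The chain was tested on simulated data. With 100 probe sets changed at each size of shift among 28914, shifts of 3 log2 units were all recovered in each of 4 contrasts. Shifts of 1.5 units were recovered in 86% of cases for kidney minus reference by OneRA, 85% for RS minus OneRA and for RS 3 ng minus 100 ng, and 64% for an interaction, with 3, 2, 7 and 5 false calls. With 1 of 24 lists shifted, camera called 1 list. The noise was drawn independently for each probe set, so correlation between genes was not simulated. Each probe set had the same SD in all groups, so the larger spread of some RS groups was not simulated either.

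Alternatives recomputed for the results were the signals as deposited, quantile normalization, pseudocounts of 1 and 128, a minimum mean signal of 500 or none, no fold minimum, only the arrays of a contrast in the fit, the replicate number as a block, each array left out in turn, all probe sets of a gene averaged, camera with an estimated correlation, and ratios without each control transcript. Added after the data were examined were a block for the array names of the kidney RS arrays and fits within each kind of name. Between any arrays of the same group at least 99.767% of signals differed, so none is a copy. A planned look at cell-level intensities could not be run because the per-array files hold probe-set values only. Figures were drawn with matplotlib 3.10.9 and tables prepared with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3.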

Results

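The series compared ways of labelling nanogram amounts of total RNA for expression arrays. Signals were measured for mouse kidney RNA and for the reference RNA by OneRA from 10 µg, by TwoRA from 10 ng and by RS from 10 ng. Kidney RNA was also labelled by RS from 100, 30 and 3 ng. Each group has 3 arrays, so n = 3 for every mean below, and differences are on the log2 scale unless a fold is given.

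The share of probe sets called present was 48.8% ± 0.63 (SD, n = 3) by OneRA, 48.8% ± 0.45 by TwoRA and 44.2% ± 0.69 by RS in the reference RNA. In kidney it was 42.0% ± 2.11 by OneRA, 44.5% ± 1.28 by TwoRA and 41.7% ± 1.03 by RS from 10 ng. Across the RS input series it was 45.7% at 100 ng, 45.2% at 30 ng and 41.1% at 3 ng. The median SD of a probe set between the 3 arrays was 0.178 by OneRA, 0.156 by TwoRA and 0.286 by RS from 10 ng in kidney, and 0.118, 0.138 and 0.190 in the reference. Of the 16556 probe sets present on all kidney arrays by OneRA, 90.6% were present on all by TwoRA and 72.7% on all by RS from 10 ng. Of the 17843 present on all RS arrays at 100 ng, 93.1%, 83.9% and 82.2% were so at 30, 10 and 3 ng.

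Kidney was compared with the reference by OneRA, the procedure with the largest input, to see which tissue differences the arrays report. Of the 10 genes with the highest differences, 5 are on the proximal tubule list. Kap, an androgen-regulated kidney protein, had a signal of 20630 ± 456 (SD, n = 3) in kidney and was present on none of the reference arrays, which makes it at least 496-fold higher (adjusted p = 3.89e-26). Slc27a2, an acyl-CoA synthetase for very long chain fatty acids, was at least 507-fold higher (adjusted p = 1.7e-27). Lrp2, the endocytic receptor megalin, was at least 236-fold higher, 7.97 ± 0.10 (SE) on the log2 scale (adjusted p = 1.08e-30). Gpx3, a secreted glutathione peroxidase, was at least 429-fold higher, and Pck1, the control enzyme of gluconeogenesis, at least 346-fold. The cytochrome Cyp2j5 was at least 355-fold higher, the tissue kallikrein Klk1 of the distal tubule at least 334-fold and the secreted nuclease Dnase1 at least 331-fold. Hao2 and Acaa1b, both peroxisomal enzymes, were at least 292-fold and 236-fold higher. In all, 3783 probe sets were higher and 5389 lower in kidney, 9172 calls of 28914 tested.

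The 10 genes with the lowest differences include 1 of the cell cycle list, Bub1. Mycl, a transcription factor of the MYC family, had a signal of 6058 ± 162 (SD, n = 3) in the reference and was present on no kidney array (14.8 ± 5.13, adjusted p = 9.78e-21). The chromatin protein Hmga2 had a signal of 12060 ± 469 (SD, n = 3) in the reference and 176 ± 12.5 in kidney, 58.2-fold lower (log2 -5.86 ± 0.20 SE, adjusted p = 1.68e-20). Bub1 of the spindle checkpoint was at least 42.1-fold lower, Anln of cytokinesis at least 34.8-fold and the tubulin Tubb6 at least 64.4-fold. Rpl39l, a paralog of a ribosomal protein, was at least 54.5-fold lower, the calcium-binding S100a4 at least 49.6-fold, and the retinoic acid-binding Crabp1 at least 41.1-fold. Gpnmb, a membrane glycoprotein of melanocytes and macrophages, was at least 42.3-fold lower, and Serpinf1, a secreted serpin, 35.7-fold.

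TwoRA and RS, both from 10 ng, gave these differences in the same directions. By TwoRA, Kap was at least 450-fold, Slc27a2 at least 415-fold, Gpx3 at least 344-fold and Lrp2 at least 185-fold higher in kidney. By RS the same genes were at least 301-fold, at least 139-fold, 119-fold and at least 117-fold higher. Klk1 was at least 336-fold higher by TwoRA and 50.6-fold by RS. Mycl was at least 31.9-fold lower by TwoRA and at least 21.3-fold by RS, and Bub1 at least 47.0-fold and at least 28.5-fold. Hmga2 had a signal of 151 ± 35.1 in kidney against 4860 ± 483 in the reference by TwoRA, and was at least 60.8-fold lower by RS. Since most of these are lower bounds, they do not rank the procedures. TwoRA called 9156 probe sets (3770 higher, 5386 lower) and RS 9169 (4256 higher, 4913 lower).

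The 4 lists of tubule segments, collecting duct included, were higher in kidney by all 3 procedures. All 27 proximal tubule genes rose by each, with median differences of 6.40 by OneRA, 6.46 by TwoRA and 6.49 by RS (camera adjusted p = 1.2e-26, 1.32e-26 and 2.24e-24). Of 9 loop of Henle genes, 9 rose by OneRA, 9 by TwoRA and 7 by RS, with medians of 5.04, 4.98 and 5.31 (adjusted p = 1.46e-09, 3.78e-09 and 2.72e-07). Umod, the main protein of normal urine, was at least 238-fold higher by OneRA and the salt transporter Slc12a1 57.3-fold. Of 7 distal tubule genes, 6, 7 and 7 rose, with medians of 3.63, 4.10 and 4.58 (adjusted p = 1.54e-06, 7.86e-07 and 3.39e-06), and Calb1, a calcium-binding protein, was at least 83.0-fold higher by OneRA. Of 12 collecting duct genes, 11 rose by OneRA, 12 by TwoRA and 8 by RS, with medians of 3.76, 3.27 and 1.92 (adjusted p = 1.94e-08, 1.96e-08 and 0.000216). Hsd11b2, which inactivates glucocorticoids in mineralocorticoid target cells, was at least 26.5-fold higher by OneRA and the anion exchanger Slc26a4 at least 26.0-fold. Of 9 genes of renal endothelium and renin cells, 8, 7 and 6 rose (adjusted p = 0.000544, 0.000704 and 0.00527). Plvap, of fenestrated endothelium, was at least 32.1-fold higher by OneRA and the receptor Tek at least 18.7-fold. The podocyte list was not called (adjusted p = 0.15, 0.15 and 0.196), although 4, 3 and 4 of its 7 genes rose, among them Podxl, 8.04-fold by OneRA. For each list in this comparison the counts adjusted over the list alone were the same as those adjusted over all genes.

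Among the other lists, cell cycle genes fell in kidney, 22 of 24 by OneRA, 21 by TwoRA and 23 by RS, with medians of -3.75, -3.67 and -2.52 (adjusted p = 1.11e-13, 1.99e-13 and 7.11e-13). Mki67, a marker of cycling cells, was at least 29.7-fold lower by OneRA and the kinase Cdk1 at least 28.6-fold. Fibroblast and extracellular matrix genes fell in 14, 14 and 12 of 14 cases, with medians of -2.95, -2.39 and -2.03 (adjusted p = 4e-10, 2.37e-09 and 1.56e-09), led by the collagen crosslinker Lox (24.9-fold by OneRA) and fibronectin Fn1 (13.9-fold). Immediate early and stress genes fell in 13, 12 and 10 of 14 cases (adjusted p = 1.36e-07, 5.21e-07 and 5.55e-07), with Fos at least 26.1-fold and Egr1 23.3-fold lower by OneRA. Translation initiation factors fell in 16, 11 and 5 of 46 cases, and 1 rose by RS (adjusted p = 3.68e-06, 0.000151 and 0.00527). The count of 5 by RS is a smaller share than the 4913 of 28914 probe sets that were lower in kidney by RS. Eif4ebp1, which restrains cap-dependent translation, was 11.2-fold lower by OneRA. Oxidative phosphorylation genes rose in 31, 20 and 59 of 91 cases, with medians of 0.82, 0.75 and 1.20. That list's adjusted p was 5.23e-12, 8.31e-11 and 3.71e-17, against 0.0874, 0.108 and 0.0448 with an estimated correlation. The succinate dehydrogenase subunit Sdhb was 3.42-fold higher by OneRA. Cytosolic ribosomal protein genes fell in 14, 9 and 9 of 45 cases (adjusted p = 5.23e-12, 1.4e-07 and 4.71e-10), against adjusted p = 0.0893, 0.205 and 0.128 with an estimated correlation.

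Smaller lists followed. Of 4 erythroid genes 3 rose by each procedure (adjusted p = 0.0151, 0.012 and 0.0407), with the heme synthesis enzyme Alas2 at least 23.9-fold higher by OneRA. Hepatocyte genes rose in 6, 5 and 4 of 9 cases with 1 falling each time (adjusted p = 0.00748, 0.00326 and 0.0454), led by the thyroxine carrier Ttr, at least 133-fold by OneRA. By RS the erythroid and hepatocyte calls each had an adjusted p = 0.0625 with an estimated correlation. The adipocyte list was called by OneRA and TwoRA (adjusted p = 0.0163 and 0.0135) and not by RS (0.066), where the interaction with OneRA was not called either (0.141), with the fatty acid carrier Fabp4 23.9-fold higher by OneRA. With an estimated correlation, all calls by OneRA and TwoRA other than those of oxidative phosphorylation and ribosomal proteins held, and by RS all but those of ribosomal proteins, erythroid and hepatocyte genes. By OneRA no call was made for leukocyte (adjusted p = 0.114), melanocyte (0.872), skeletal muscle (0.559), germ cell and gonad (0.451), simple epithelium (0.677), embryonic (0.285), heat shock (0.785), histone (0.227) or proteasome genes (0.421), nor by TwoRA or RS. In skeletal muscle and heat shock the median was below 0 and the mean and the test above it. Single members of these lists differed all the same, such as the macrophage gene Cd68, 7.13-fold lower, the adhesion protein Cdh1, 36.3-fold higher, and the keratin Krt18, 9.71-fold lower, all by OneRA.

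**Figure D1:**
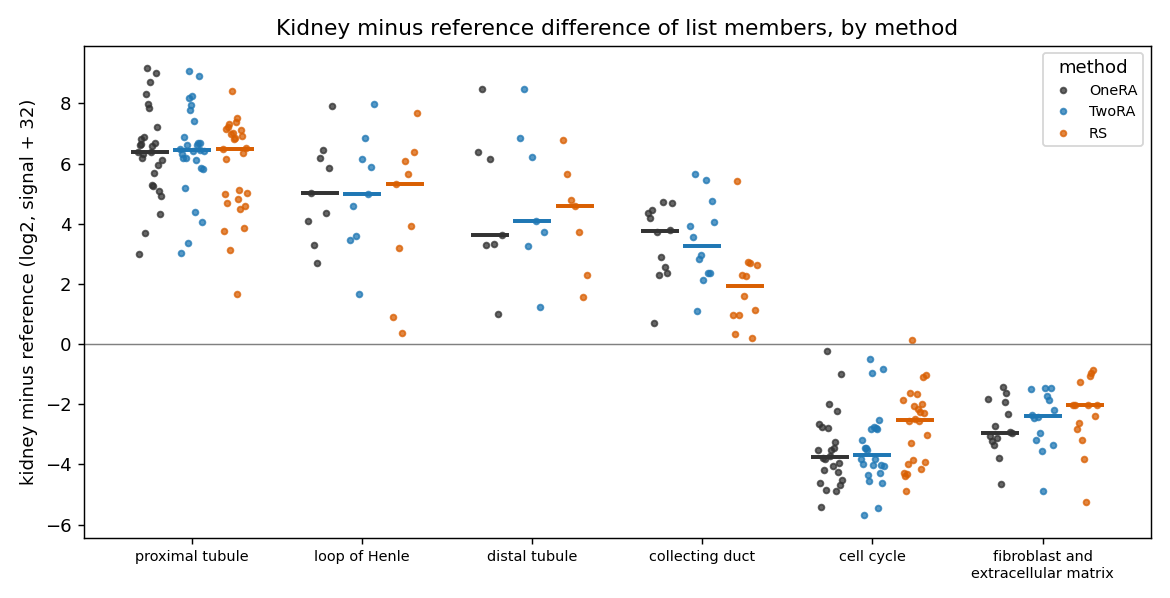
Kidney minus reference differences (vertical axis, log2 of signal plus 32) of the members of 6 gene lists by OneRA, TwoRA and RS, 1 point per gene, with bars at the medians. The collecting duct median lies at 3.76 by OneRA, 3.27 by TwoRA and 1.92 by RS, and the cell cycle median at -3.75, -3.67 and -2.52.

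Whether the procedures report the same tissue differences was asked across the 28914 probe sets, which are not independent replicates. Between OneRA and TwoRA the correlation of the kidney minus reference differences was 0.938 (Pearson) and 0.891 (Spearman). Of the OneRA calls, 7262 (79.2%) were also called in the same direction by TwoRA and 6 in the opposite direction, where chance overlap would give 1497. Between OneRA and RS the correlations were 0.828 and 0.751, with 5980 calls (65.2%) shared and 20 opposite. TwoRA and RS, which used the same input, correlated at 0.854 and 0.786, with 6180 calls shared and 14 opposite. Probe sets of low signal lowered these values. Between OneRA and RS the Pearson correlation was 0.603 for mean signals of 100 to 300, 0.829 for 300 to 1000 and 0.934 from 1000 upward, and between OneRA and TwoRA it was 0.837, 0.945 and 0.979.

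TwoRA was compared with OneRA within kidney RNA, where the labels give 1 source of RNA and differ in procedure and input. Malat1, a long noncoding RNA of the nucleus, was 10.6-fold higher by TwoRA, at 10400 ± 1090 against 953 ± 130 (SD, n = 3; adjusted p = 3.8e-17). Mapre2, a microtubule-binding protein, was 9.33-fold higher, the splicing regulator Nsrp1 at least 8.46-fold and the chaperone Hspa4 7.69-fold, although 1 of 4 Hspa4 probe sets was called the opposite way. The demethylase Kdm6b was called higher but was present on no array of either group. Ube2s, a ubiquitin-conjugating enzyme, was 13.6-fold lower by TwoRA and the protease Ctse 11.4-fold. The LIM domain protein Csrp1 was at least 10.8-fold lower, the splicing repressor Ptbp1 9.53-fold and the kinase scaffold Mapk8ip1 at least 9.24-fold. In the reference RNA Malat1 was 6.35-fold, Mapre2 8.74-fold and Hspa4 4.77-fold higher, and Ptbp1 9.54-fold, Csrp1 9.73-fold and Ube2s 4.12-fold lower, while Ctse was 1.92-fold below OneRA (adjusted p = 5.6e-05), short of the 2-fold minimum. With quantile normalization Ctse was called, at a log2 difference of -1.217 (adjusted p = 1.25e-06). TwoRA called 1422 probe sets higher and 2590 lower in kidney, and 1151 higher and 2527 lower in the reference. With quantile normalization these counts of probe sets were 1954 and 2052, and 1670 and 2224. No list was called in kidney, where the lowest adjusted p was 0.166. In the reference, immediate early and stress genes fell in 3 of 14 cases, among them Fosb, 4.07-fold (adjusted p = 0.0497, and 0.285 with an estimated correlation). Ribosomal protein genes shifted down by a median of -0.22 with 1 member, Rpl14, called higher (adjusted p = 0.00102, and 0.817 with an estimated correlation), a shift of -0.01 with quantile normalization (adjusted p = 0.772). Oxidative phosphorylation genes shifted up by 0.19 with 4 members higher and 4 lower (adjusted p = 0.0228, and 0.845 with an estimated correlation), which quantile normalization did not call (0.909).

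RS and TwoRA, the procedures with 10 ng of input, were compared within kidney RNA to ask whether they report the same levels. Thoc1, of the complex that couples transcription to mRNA export, was at least 72.5-fold higher by RS, with a signal of 6916 ± 403 against 66.1 ± 25.1 (SD, n = 3; log2 6.18, adjusted p = 1.93e-23). The deubiquitinase Otud5 was at least 65.8-fold higher, the nuclear pore protein Seh1l 58.1-fold and the acyltransferase Lpcat1 at least 56.8-fold. The chemokine scavenger Ackr4 was 52.7-fold higher, the mitochondrial RNA-binding Ptcd1 at least 51.8-fold and the trafficking GTPase Rab2a 49.3-fold. Pigb, of GPI anchor synthesis, was at least 48.7-fold higher, the transcription regulator Rai2 43.1-fold and the histone chaperone partner Ubn1 at least 42.5-fold. For Thoc1, Seh1l, Lpcat1, Rab2a and Ubn1, another probe set of the same gene was called the opposite way. A gene's probe set was chosen by its mean signal over all arrays, most of them RS arrays. The probe sets of the genes highest by RS are thus partly picked for being bright by RS. Pik3cd, a catalytic subunit of phosphoinositide 3-kinase, was at least 69.6-fold lower by RS (log2 -6.12 ± 0.22 SE, adjusted p = 1.21e-19). The small heat shock protein Hspb1 was 25.3-fold lower, the ankyrin repeat protein Gpank1 at least 28.1-fold, the splicing factor Srrm2 at least 24.0-fold and the actin-binding Triobp at least 21.7-fold. Pacsin3 of endocytosis was at least 20.9-fold lower, Ap5z1 of endosomal transport at least 20.5-fold and the nucleolar Rbm28 at least 20.2-fold. The collagen-modifying Plod3 was lower too, at 10.3 ± 3.15 against 814 ± 65.9. Another Srrm2 probe set was called the opposite way, and 3110021A11Rik was called lower while present on no array of either group. In the reference RNA the same probe sets of Thoc1, Otud5 and Rab2a were 77.1-fold, at least 77.4-fold and 73.1-fold higher by RS, and Pik3cd at least 53.1-fold lower.

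RS was also compared with OneRA in kidney, with the same RS arrays as against TwoRA, so genes that recur are not independent findings. Otud5 was at least 103-fold higher (4757 ± 494 against 14.6 ± 4.80, SD, n = 3), Seh1l at least 65.7-fold, Thoc1 at least 62.6-fold, Rai2 59.6-fold and Lpcat1 at least 59.3-fold, with other probe sets of Seh1l, Thoc1 and Lpcat1 called the opposite way. Pik3cd was at least 73.9-fold lower, Enpp5, a membrane phosphodiesterase, at least 36.6-fold, Gpank1 at least 35.2-fold, Triobp at least 31.8-fold and Plod3 at least 28.2-fold. RS called 5697 probe sets higher and 8916 lower than OneRA in kidney, and 7050 and 7204 with quantile normalization. In the reference it called 5758 higher and 9367 lower, and 6989 and 7895 with quantile normalization. Against TwoRA it called 5820 higher and 7683 lower in kidney, and 5929 and 8416 in the reference. With quantile normalization these were 6259 and 6897, and 6507 and 7649. These contrasts shift all probe sets together, and quantile normalization moved that shift by more than 0.1. The median of all probe sets went from -0.31 to -0.05 for RS minus OneRA in kidney and from -0.34 to -0.09 in the reference. For RS minus TwoRA it went from -0.19 to -0.09 and from -0.23 to -0.12, and for TwoRA minus OneRA from -0.11 to 0.05 and from -0.08 to 0.05. The differences between procedures recurred in both RNAs. Across probe sets they correlated between kidney and reference at 0.768 for TwoRA minus OneRA, 0.862 for RS minus OneRA and 0.867 for RS minus TwoRA.

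Some gene lists were called lower by RS with the preset correlation only. Over all 28914 probe sets, RS called 8916 lower than OneRA and 7683 lower than TwoRA in kidney, and 9367 and 8416 in the reference. The counts of members below are to be read against those shares. Where a bracket holds a pair of adjusted p-values, the second is with an estimated correlation. Oxidative phosphorylation genes fell in 35 of 91 cases and rose in 3 by RS against OneRA in kidney (median -0.78, adjusted p = 0.00011, and 0.85 with an estimated correlation). Uqcr11, a subunit of complex III, was 6.20-fold lower, whereas Sdhd, of complex II, was 9.12-fold higher. Against TwoRA in kidney 39 fell and 1 rose (adjusted p = 1.41e-06, and 0.751 with an estimated correlation). In the reference 48 fell and 2 rose against OneRA (adjusted p = 5.17e-07, and 0.697 with an estimated correlation), and 54 fell and 2 rose against TwoRA (4.61e-10, and 0.547). Proteasome genes fell by RS against TwoRA in 16 of 38 cases in kidney with 2 rising (adjusted p = 0.00251, and 0.329 with an estimated correlation), such as Psmb5, 4.19-fold. In the reference 19 fell against TwoRA (4.28e-05, and 0.187) and 15 against OneRA (0.00144, and 0.633). Proximal tubule genes fell by RS in kidney in 12 of 27 cases against OneRA (adjusted p = 0.00326, and 0.246 with an estimated correlation) and in 10 against TwoRA (0.0112, and 0.329). The urate transporter Slc22a12 was 13.3-fold lower than by OneRA and 7.99-fold lower than by TwoRA. Ribosomal protein genes fell by RS against TwoRA in kidney in 8 of 45 cases and rose in 3 (adjusted p = 0.0315, and 0.797 with an estimated correlation). Rplp0 was 4.92-fold lower and Rpl27a 23.3-fold higher. Those 8 are a smaller share than that of all probe sets called lower in the same comparison. In the reference, ribosomal protein genes shifted down against OneRA (0.00105, and 0.795) and TwoRA (0.0337, and 0.804). Collecting duct genes fell in 8 of 12 cases against OneRA in kidney, but that list was not called (adjusted p = 0.0643), and quantile normalization called it (0.0393). In the same comparison quantile normalization also called the ribosomal protein and proteasome lists (0.00609 and 0.000358). None of the list calls between procedures held with an estimated correlation.

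Differences between procedures in the kidney minus reference difference were tested directly as interactions. The lowest between RS and OneRA included Cdh16 and Apoe. Cdh16, the kidney cadherin, differed between kidney and reference by 7.91 by OneRA and 3.70 by RS, an interaction of -4.21 ± 0.28 (SE; adjusted p = 9.52e-12). Its kidney signal was 12880 ± 516 (SD, n = 3) by OneRA, 15070 ± 840 by TwoRA and 3712 ± 1330 by RS. Apoe, a lipoprotein component, had an interaction of -4.14, with kidney signals of 6766 ± 373, 10420 ± 226 and 564 ± 36. Ppara, a regulator of fatty acid oxidation, fell from 5.91 to 1.69 (interaction -4.22 ± 0.32, adjusted p = 1.54e-10). The membrane proteases Hpn and Prss8 had interactions of -4.13 and -4.07. In the other direction Prepl, a serine peptidase, differed by 0.24 by OneRA and by 4.66 by RS (interaction 4.42 ± 0.20, adjusted p = 1.84e-15). Rai2 differed by 1.32 and 5.32, the desmosomal cadherin Dsg2 by 0.59 and 4.53, and the signalling ligand Wnt4 by -3.42 and 0.62. With a pseudocount of 1 the Rai2 interaction was 1.64 and not called (adjusted p = 0.0922). The immunoglobulin gene Igk-V21 had an interaction of 4.07. Of 28914 probe sets 2147 had a higher and 1915 a lower difference by RS than by OneRA, 4062 in all.

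RS against TwoRA gave 3313 interactions, 1735 higher and 1578 lower. Hbb-b2, a globin chain, had the highest (5.39 ± 0.39 SE, adjusted p = 7.62e-11), although its other probe set was called the opposite way. Dnm1, a dynamin, followed with 4.40, then Wnt4 with 3.96, Igk-V21 with 3.94 and the phosphate transporter Slc34a2 with 3.83. The lowest were the oxygen carrier Mb (-5.05 ± 0.27 SE, adjusted p = 2.31e-13), Apoe (-4.96), Cdh16 (-4.54), Phyhipl (-4.23) and Hpn (-4.03). TwoRA against OneRA gave 576, 312 higher and 264 lower (922, 442 and 480 with only the arrays of the contrast in the fit). The integrin Itga5 had the highest (2.85 ± 0.41 SE, adjusted p = 7.03e-05), with kidney minus reference differences of -4.30 by OneRA and -1.45 by TwoRA. The pseudokinase Trib1 had an interaction of 2.62, the cardiac myosin Myh6 2.53 and the water channel Aqp12 2.40, with Sec14l3, a lipid carrier, close by at 2.42. Habp2, a plasma protease, had the lowest (-3.29 ± 0.46 SE, adjusted p = 6.03e-05), with another of its probe sets called the opposite way. Atp6v0a4, a proton pump subunit of intercalated cells, went from 4.91 by OneRA to 1.77 by TwoRA (interaction -3.14), Pigt of GPI anchor transfer had -2.83, and Ctse and Mroh2a had -2.57 each.

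Collecting duct genes had the largest list interaction between RS and OneRA, with 7 of 12 lower by RS (median -1.71, adjusted p = 5.05e-06, and 0.00258 with an estimated correlation). Aqp2, the vasopressin-regulated water channel, differed between kidney and reference by 4.36 by OneRA, 3.91 by TwoRA and 0.98 by RS, the last not called (interaction with OneRA -3.38 ± 0.35 SE, adjusted p = 4.73e-08). The water channel Aqp3 had an interaction of -3.83, and the sodium channel subunits Scnn1g and Scnn1b had -2.67 and -2.17. Proximal tubule genes were lower in 10 of 27 cases and higher in 1 (median -0.58, adjusted p = 0.000356, and 0.0323 with an estimated correlation), with Slc22a12 at -3.60. Cell cycle genes, which are lower in kidney, differed less by RS, with 11 of 24 interactions called above 0 and 1 called below, or 11 and 3 adjusted over the list alone (median 0.84, adjusted p = 0.000356, and 0.00988 with an estimated correlation). The mitotic kinase Plk1 had an interaction of 3.14 and the replication licensing factor Cdc6 2.19. Translation initiation factors shifted up, with 5 of 46 called (adjusted p = 0.0014, and 0.0163 with an estimated correlation). Calls lost with an estimated correlation were oxidative phosphorylation (adjusted p = 1.57e-05, and 0.337), proteasome (0.00135, and 0.144), loop of Henle (0.0433, and 0.144), fibroblast and extracellular matrix (0.0433, and 0.242) and ribosomal protein genes (0.0433, and 0.609). The ribosomal median went from 0.20 to -0.01 with quantile normalization.

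RS against TwoRA, which shares the RS arrays with the comparison above, called the collecting duct (7 of 12 lower, median -1.41, adjusted p = 3.95e-08), proximal tubule (11 lower, 1 higher, adjusted p = 0.000227), cell cycle (10 higher, 2 lower, adjusted p = 0.0015) and hepatocyte lists (3 of 9 lower, adjusted p = 0.0133). With an estimated correlation these had adjusted p = 0.00059, 0.0321, 0.023 and 0.0412. The fibrinogen chain Fgg had an interaction of -1.95 there and Ttr -1.79. Also called were oxidative phosphorylation (adjusted p = 1.66e-09), proteasome (0.00469), loop of Henle (0.0401), distal tubule (0.0335), simple epithelium (0.0335) and adipocyte genes (0.047), each with an adjusted p = 0.128 with an estimated correlation. Quantile normalization did not call the loop of Henle (0.0542). TwoRA against OneRA shifted ribosomal protein genes by a median of 0.27 with 0 members called (adjusted p = 1.89e-08, and 0.544 with an estimated correlation), and with quantile normalization by 0.04 with the test in the opposite direction (0.983). Fibroblast and extracellular matrix genes shifted up with 0 called (0.0207, and 0.355 with an estimated correlation). Translation initiation factors shifted up with 2 called, Eif4ebp1 and Eif3e (0.016, and 0.111 with an estimated correlation). Quantile normalization did not call Eif3e, at an interaction of 0.922.

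The RS input series asked how kidney signals change from 100 ng down to 3 ng. At 3 ng Mt2, a metallothionein, was 2.94-fold higher than at 100 ng (8298 ± 191 against 2801 ± 134, SD, n = 3; adjusted p = 6.63e-10), and Pfdn2, a cochaperone subunit, 4.10-fold. Spin4, a histone reader, was 3.61-fold higher, the receptor P2ry10b 3.12-fold and 2210406O10Rik, a transcript of unknown function, 3.05-fold. Dpp6, Smr2, Pak3, Alpk3 and Ckm were called higher but were present on no array of either group. Polrmt, the mitochondrial RNA polymerase, was 5.59-fold lower at 3 ng, the RNA polymerase II subunit Polr2i 5.32-fold and Hcfc1r1, a regulator of a transcriptional cofactor, 5.55-fold (log2 -2.47 ± 0.16 SE, adjusted p = 5.65e-11). The proton pump subunit Atp6v0a1 was at least 4.49-fold lower, Ttc27 at least 4.28-fold, the kinase Map2k2 at least 3.97-fold and the capping enzyme Rngtt at least 3.87-fold. Ticam1, an adaptor of Toll-like receptors, was at least 3.65-fold lower and the asparaginase Asrgl1 at least 3.63-fold, and Wfdc17 was called lower with no array present. Polrmt was 2.84-fold lower already at 30 ng and 5.10-fold at 10 ng, Polr2i 2.12-fold (not called with quantile normalization, log2 -0.942, adjusted p = 0.000743) and 2.90-fold, and Pfdn2 2.90-fold and 3.54-fold higher. At 30 ng Mt2 was 1.44-fold above (adjusted p = 0.0102) and Hcfc1r1 1.97-fold below 100 ng (adjusted p = 0.000651), short of the 2-fold minimum, and at 10 ng they were 2.78-fold higher and 3.55-fold lower.

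Calls rose in number as the input fell. There were 150 at 30 ng (35 higher, 115 lower), 751 at 10 ng (364 and 387) and 1649 at 3 ng (853 and 796). With quantile normalization the counts at 10 and 3 ng were 212 higher and 483 lower, and 516 and 1005. The balance also moved with the treatment of dim probe sets. With a minimum mean signal of 500 it was 5 higher and 60 lower at 30 ng, 29 and 177 at 10 ng, and 111 and 367 at 3 ng. With no filter it was 45 and 116, 637 and 430, and 1490 and 883. Single arrays moved the smaller counts, since at 30 ng the count was 268 without 100 ng replicate 1 and 91 without 100 ng replicate 2. At 10 ng it was 1250 without 10 ng replicate 2 and 506 without 100 ng replicate 2. With only the arrays of the contrast in the fit, the counts were 130, 164 and 1202 at 30, 10 and 3 ng. At 10 ng these were 31 higher and 133 lower. The main fit gives all groups 1 shared spread per probe set, whereas the median SD differed between inputs. It was 0.21 at 100 ng, 0.19 at 30 ng, 0.29 at 10 ng and 0.28 at 3 ng. The names in the array headers divide the kidney RS arrays into a kind starting with Kidney (2, 1, 2 and 1 of 3 at 100, 30, 10 and 3 ng) and others. With this as a block the counts were 167, 770 and 1577. Within the Kidney names they were 167, 959 and 2503, and within the others 308, 1114 and 1834.

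Oxidative phosphorylation, ribosomal protein and proteasome genes had medians below 0 at 30, 10 and 3 ng. All 3 contrasts subtract the same 100 ng arrays, so these medians are not independent of each other, and none of the calls held with an estimated correlation. At 3 ng 6 of 91 oxidative phosphorylation genes fell (median -0.45, adjusted p = 5.34e-17, and 0.109 with an estimated correlation), and 82 of 91 lay below 0. Uqcc2, an assembly factor of complex III, was at least 3.70-fold lower, the complex I subunit Ndufs7 2.52-fold and the ATP synthase subunit Atp5j2 2.26-fold. Cox8b was at least 2.32-fold lower, and Uqcr11 and Uqcrq, named after their values were seen, 2.16-fold and 2.12-fold. The median was -0.32 at 30 ng with 1 called (4.39e-17, and 0.337 with an estimated correlation) and -0.32 at 10 ng with 6 called (5.98e-13, and 0.218). With the array names as a block the medians at 30, 10 and 3 ng were -0.32, -0.32 and -0.47. Within the Kidney names they were -0.35, -0.26 and -0.45, and within the others -0.28, -0.35 and -0.45. Ribosomal protein genes shifted by -0.23, -0.13 and -0.32 at 30, 10 and 3 ng (adjusted p = 1.11e-08, 0.000268 and 7.03e-09, and 0.367, 0.572 and 0.236 with an estimated correlation), with Rpl35 2.01-fold lower at 3 ng. Proteasome genes shifted by -0.15, -0.20 and -0.38 (adjusted p = 0.00189, 0.000268 and 4.21e-06, and 0.337, 0.218 and 0.0546 with an estimated correlation), with 0, 1 and 0 of 38 called. Within the 2 kinds of names the medians at 3 ng were -0.26 and -0.30 for ribosomal protein genes and -0.29 and -0.34 for proteasome genes.

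Further lists were called at 3 ng only with the preset correlation, and the second p in each bracket is with an estimated correlation. Translation initiation factors shifted down with Eif4e2 and Eif3c lower (adjusted p = 0.00766, and 0.0546 with an estimated correlation), which quantile normalization did not call (0.0557). Proximal tubule genes shifted by -0.30 with 0 of 27 called (0.0193, and 0.144), and fibroblast and extracellular matrix genes by -0.44 with Postn, a matrix protein, lower (0.0267, and 0.218). Embryonic genes shifted up by 0.52 with the mRNA-binding Igf2bp3 2.35-fold higher (0.023, and 0.144), and immediate early and stress genes by 0.21 with Fos and Junb called though present on no array (0.0267, and 0.109). Quantile normalization called neither of the last pair (0.0619 for each).

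Coverage of transcripts was compared by the 3′ to 5′ ratio of 4 control transcripts. Its mean log2 in kidney was 0.81 ± 0.14 (SD, n = 3) by OneRA, 2.05 ± 0.14 by TwoRA and 2.40 ± 0.19 by RS from 10 ng, and in the reference 0.50 ± 0.04, 1.09 ± 0.17 and 1.38 ± 0.17. Permuting within both RNAs, TwoRA was above OneRA by 0.92 and RS above OneRA by 1.24 (exact two-sided p = 0.005 for each, the smallest these labelings allow). RS was above TwoRA by 0.32 (exact p = 0.02), but that difference reversed to -0.71 in kidney and -0.54 in the reference without transferrin receptor, whose 5′ probe set was present on no RS array. Without it RS minus OneRA was 1.04 in kidney and 0.16 in the reference. The transcripts did not all follow the mean. Over both RNAs the transferrin receptor ratio differed by 0.01 between TwoRA and OneRA (exact p = 0.935), and that of pyruvate carboxylase by -0.82 between RS and OneRA (exact p = 0.12), with -1.82 in the reference, where its 3′ probe set was present on no RS array. Beta-actin alone gave a ratio of 0.22 by OneRA, 1.46 by TwoRA and 2.02 by RS in kidney, and Gapdh -0.36, 1.33 and 0.77. Along the input series the mean was 2.29 at 100 ng, and the differences from it were -0.28 at 30 ng (exact p = 0.2), 0.12 at 10 ng (exact p = 0.5) and -0.36 at 3 ng (exact p = 0.3), where no p below 0.1 is possible.

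**Figure D2:**
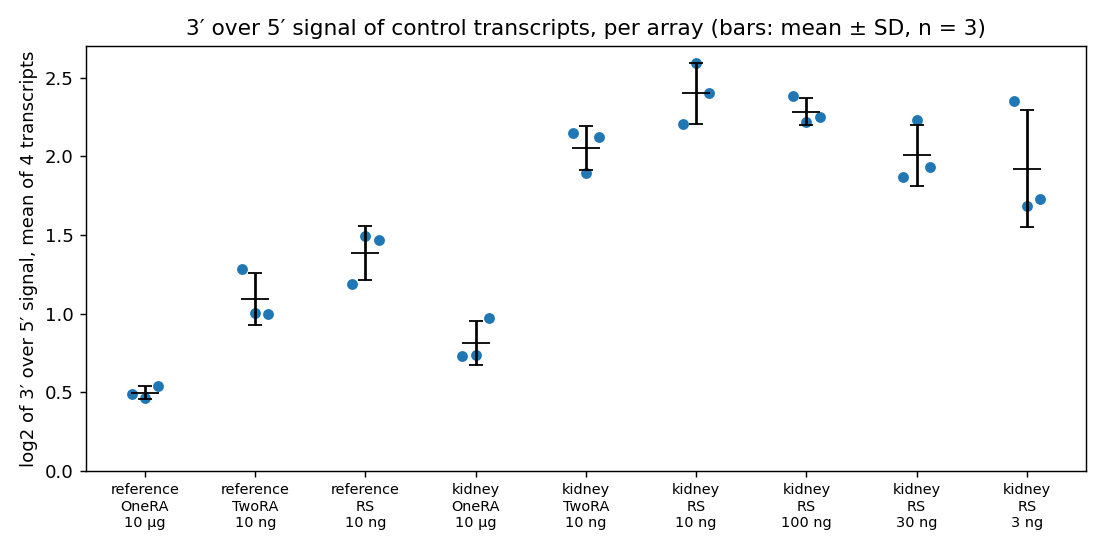
Log2 ratio of 3′ to 5′ signal (vertical axis), averaged over 4 control transcripts, for each array (points) of the 9 groups, with mean and SD (bars, n = 3). OneRA lies lowest in both RNAs, at 0.81 in kidney and 0.50 in the reference.

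Control probe sets for 18S ribosomal RNA, which carries no long poly(A) tail, also differed between procedures. Their 5′ site in kidney had signals of 109 ± 20.6 (SD, n = 3) by OneRA, 14920 ± 1650 by TwoRA and 454 ± 396 by RS from 10 ng. The middle site had 83.5 ± 24.7, 11590 ± 1050 and 17950 ± 1930, and the 3′ site 263 ± 55.4, 11110 ± 1310 and 706 ± 399.

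**Figure D3:**
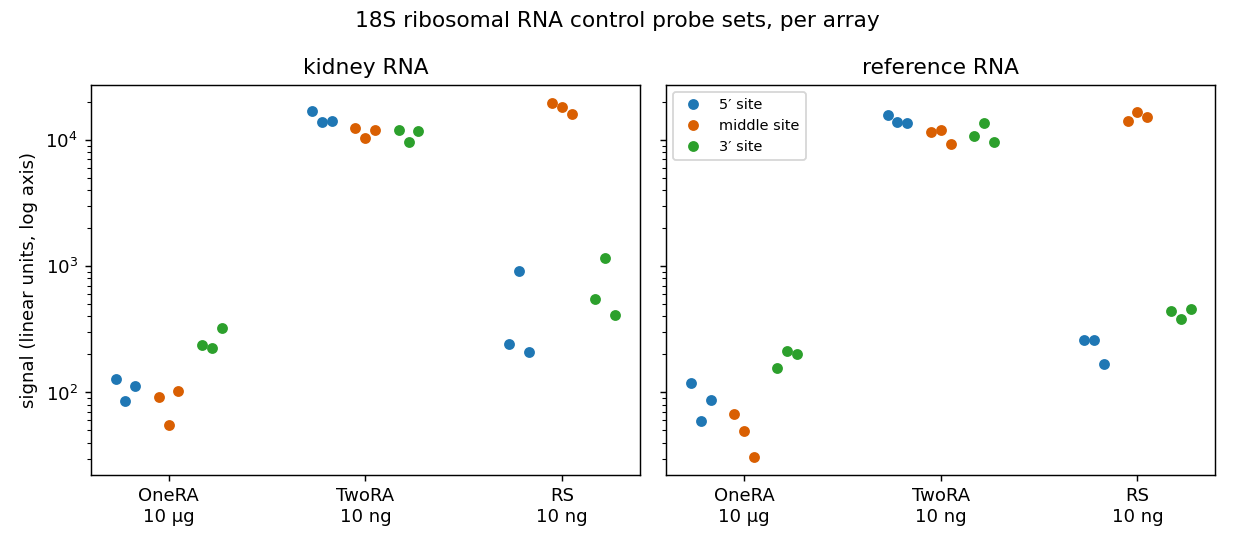
Signals (vertical log axis, linear intensity units) of the 18S ribosomal RNA control probe sets at their 5′, middle and 3′ sites, 1 point per array, for OneRA, TwoRA and RS from 10 ng in kidney and reference RNA. By TwoRA all 3 sites are bright, and by RS the middle site alone.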

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

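The tests of 18S ribosomal RNA were chosen only after the results were seen. So were the tests of the oxidative phosphorylation shift by array name and after quantile normalization. So were the matched lists for proximal tubule, cell cycle, ribosomal protein and proteasome genes, and the splits with the average procedure effect taken out. What each other test in this part would show was written down before its own result was seen, as it was for the array names. The gene lists, contrasts, thresholds and splits were chosen before the data were examined.

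The kidney minus reference difference itself differed between procedures, by the interaction test, for 576 probe sets between TwoRA and OneRA, 4062 between RS and OneRA and 3313 between RS and TwoRA. Of 100 splits of the arrays, 13, 14 and 15 gave as many calls, the real one included, with highest other counts of 10226, 16790 and 16363, so by this test chance is not excluded for any of the 3 counts. Counts several times the real one point to a structure of the arrays. All 12, 13 and 14 other splits that reached the real count kept a whole procedure together within at least 1 RNA. The difference between procedures itself then entered the interaction. The highest count of the splits that mixed procedures in both RNAs was 1 each time. In a second test the procedure effect averaged over both RNAs was taken out before the arrays were split. Only 1 of 100 splits, the real one, then gave as many calls in each of the 3 interactions, with real counts of 570, 4061 and 3308 and highest other counts of 16, 1241 and 746. That test was chosen because of the outcome of the first. In splits that mix procedures the interaction itself widens the spread, which lowers their counts. The second test is therefore not taken to exclude chance.

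For each contrast of 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real split alone (1 of 10) gave as many calls. Every other split mixes the groups, so a large difference between them widens the spread and leaves few calls by construction. Kidney minus reference gave 9172 calls by OneRA against a highest other of 1, 9156 by TwoRA against 1 and 9169 by RS against 12. Within kidney the counts were 4012 against 5 for TwoRA minus OneRA, 14613 against 1 for RS minus OneRA and 13503 against 1 for RS minus TwoRA. Within the reference they were 3678 against 4, 15125 against 1 and 14345 against 1. The input series gave 150 against 5 at 30 ng, 751 against 323 at 10 ng and 1649 against 57 at 3 ng. A split that follows the array names gave 5 calls at 30 ng and 57 at 3 ng, and at 10 ng no split follows them.

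Collecting duct genes had a smaller kidney minus reference difference by RS than by OneRA (median interaction -1.71), which the test of the difference itself picked out. Loss of detection in kidney by RS is argued against by the 9 of 12 members present on all kidney arrays by both procedures. Those members had a median of -2.01 (SE 0.69). The reference signals, which also enter the difference, were not looked at in this test. A shrinkage of all large tissue differences by RS would give a list matched on its OneRA differences a median of -0.33. The collecting duct list lay at percentile 0.02 of 10000 such lists, whose 5th percentile was -0.93. Such lists are random genes, so their range leaves out correlation within a list and the percentile is no p-value. The labels give each RNA 1 source in all procedures, so the design holds no biological explanation and none was tested. What remains open is how much of the list's shift the reference signals carry. Also open is a property of these transcripts or of their probe sets that may set the yield by RS. Neither was tested.

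Proximal tubule genes (median interaction -0.58) and cell cycle genes (0.84) were picked out by the same test. Lists matched on the OneRA difference had medians of -0.43 and 0.60, which place these lists at percentiles 30.7 and 82, within the range of the matched lists.

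Oxidative phosphorylation genes were lower by a median of -0.45 at 3 ng than at 100 ng of kidney RNA by RS, with an adjusted p of 0.109 when the correlation between genes was estimated. A loss of bright probe sets at low input is argued against by 10000 lists matched on signal. They had a median of 0.05 and a 5th percentile of -0.02, and placed this list at percentile 0. Those lists were random genes, so their range leaves out correlation within a list and the percentile is no p-value. Ribosomal protein and proteasome genes lay at percentiles 0 and 0.01 in the same test, so this outcome is not particular to oxidative phosphorylation. The array names do not account for the lower oxidative phosphorylation median, since with the names as a block it was -0.47. Within each kind of name the median was -0.45, with a single array at 1 of the inputs. The scaling does not account for it either, since quantile normalization gave -0.46. The labels give 1 source of kidney RNA at all inputs, so no biological explanation was tested. An effect of input that differs between transcripts stays open as a candidate explanation.

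Signals of the 18S control probe sets, which no comparison of genes used, were far higher by TwoRA than by OneRA. The folds are ratios of geometric means. In kidney the 5′ site was 138-fold, the middle site at least 143-fold and the 3′ site 42.7-fold higher, and in the reference 168-fold, at least 231-fold and 59.2-fold. RS raised the middle site at least 221-fold in kidney and at least 322-fold in the reference over OneRA, where the middle site was present on none of the arrays. The 9 hybridisation spike probe sets, for transcripts foreign to the mouse, also rose by RS over OneRA, by a median of 3.53-fold in kidney and 4.59-fold in the reference, against 1.19 and 0.879 by TwoRA.

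Scaling of the arrays would move the spikes as much, and the fold of the middle site was at least 30.2 times that of the spike probe set that rose most. By RS the highest ratio of an end site's fold over OneRA to that of the middle site was 0.0151. Background limits the OneRA signal of some end sites too, so that ratio is no bound. The kidney 3′ site alone was present on all OneRA arrays of its group, and its ratio was at most 0.0112, which argues against copying of the whole 18S RNA by RS. Copying by RS as even as that by TwoRA is argued against by the folds of RS over TwoRA, where every site was present on all arrays and the highest ratio of an end site to the middle site was 0.0374. By TwoRA over OneRA the lowest ratio was 0.256, which decides nothing, since background limits both of its parts, and whether TwoRA copied the whole 18S RNA stays open. Why the middle site alone is bright by RS stays open, and 18S RNA was not measured apart from labelling. No biological explanation was tested, since the labels give each RNA 1 source.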

How the results depend on the processing

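The array-name block and the fits within each kind of array name were chosen only after the results were seen, and the other alternatives were planned. The signals as deposited, quantile normalization, no filter on low values and the replicate block moved none of the 15 counts of called probe sets by over 1.5 times. With the replicate number as a block, RS 3 ng minus 100 ng gave 1660 calls and RS minus OneRA in kidney 14615. The labels tie the numbers to nothing shared, and in no contrast did all 3 pairs of arrays with the same number correlate above 0.1, though 2 did at RS 30 ng and at RS 10 ng minus 100 ng. All 6 arrays correlated best with their own number in RS 10 ng and RS 3 ng minus 100 ng and in RS minus OneRA in kidney, a hint from the data and not from the design. Of 1085 values of named genes, none reversed in any of these settings or with another pseudocount, no fold minimum or an array left out. The larger pseudocount took 156 of them below the threshold, quantile normalization 43, a pseudocount of 1 took 28 and no filter 3. Among calls given in the report, quantile normalization lost Polr2i at RS 30 ng (-0.942), Junb at RS 3 ng (0.829) and the interaction of Eif3e between TwoRA and OneRA (0.922). A pseudocount of 1 lost Cox8b at RS 3 ng (adjusted p = 0.0638) and the interaction of Rai2 between RS and OneRA (adjusted p = 0.0922). The larger pseudocount lost more of them, Polr2i at RS 30 ng (-0.984) included. At RS 3 ng it lost Rpl35 (-0.994), Igf2bp3 (0.656), Postn (-0.567), Cox8b (-0.795), Fos (0.855) and Junb (0.561). Smr2 (0.973), Pak3 (0.793), Alpk3 (0.883) and Ckm (0.897) were lost there too. So were the kidney minus reference calls of Rai2 by OneRA (0.498) and of Itga5 by TwoRA (-0.629). With an array left out, 7159 values kept their side of the threshold, 235 fell below it and 16 passed it. No gene named as highest or lowest in its own contrast lost its call. Genes named only as members of a list, and named genes in further contrasts, are part of these counts. The 235 losses lie among them and are not listed 1 by 1 here. Of the list results, an estimated correlation took 50 below the threshold and left 310 where they were, quantile normalization 8 (with 10 added) and averaged probe sets 13 (with 8 added). The planned spread of cell-level intensities was not run, because the files hold probe-set values only.

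A pseudocount of 1, which gives weight to dim probe sets, raised the calls to 1148 at RS 10 ng and 2478 at RS 3 ng. The larger pseudocount lowered them to 34 at 30 ng, 132 at 10 ng and 368 at 3 ng, and to 2379 in kidney and 2348 in the reference for TwoRA minus OneRA. The folds shrink by construction as the pseudocount grows.

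A minimum mean signal of 500 tests fewer probe sets, which by itself lowers each count. Kidney minus reference then gave 4637 calls by OneRA, 4551 by TwoRA and 4564 by RS. In kidney TwoRA minus OneRA gave 1768, RS minus OneRA 6321 and RS minus TwoRA 6284, and in the reference 1473, 6642 and 6684. The interactions gave 222 for TwoRA against OneRA, 1418 for RS against OneRA and 1216 for RS against TwoRA, and the input series 65, 206 and 478 at 30, 10 and 3 ng.

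Without the fold minimum, which by construction can only add calls, kidney minus reference gave 16052 by OneRA, 16148 by TwoRA and 16027 by RS. TwoRA minus OneRA gave 10764 in kidney and 10250 in the reference, and RS minus TwoRA in kidney 20334. The interactions gave 1018, 6740 and 5710, and the input series 966, 3376 and 7231.

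With only the arrays of the contrast in the fit, the interaction of TwoRA against OneRA gave 922 calls. RS 10 ng minus 100 ng gave 164. The main fit shares 1 spread per probe set between all groups, which understates it for noisier groups and overstates it for quieter ones. The median SD ran from 0.118 by OneRA in the reference to 0.286 by RS from 10 ng in kidney. How far this accounts for the changed counts was not tested. Within the kidney RS arrays of other names, RS 30 ng minus 100 ng gave 308, and within the names starting with Kidney RS 3 ng minus 100 ng gave 2503, each on fewer arrays. Fits with a single array in a group assume that it varies like the other groups. With an array left out, RS 30 ng minus 100 ng ranged from 91 (without 100 ng replicate 2) to 268 (without 100 ng replicate 1). RS 10 ng minus 100 ng ranged from 506 (without 100 ng replicate 2) to 1250 (without 10 ng replicate 2).

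The correlation of tissue differences between TwoRA and OneRA was 0.929 with a pseudocount of 1, 0.974 with a minimum signal of 500 and 0.906 with no filter. Between RS and OneRA it was 0.806, 0.916 and 0.769, and between RS and TwoRA 0.830, 0.924 and 0.803. The correlation of procedure effects between the RNAs was 0.731, 0.848 and 0.692 for TwoRA minus OneRA, 0.783 with the larger pseudocount and 0.760 with quantile normalization. For RS minus OneRA it was 0.912 with a minimum signal of 500 and 0.833 with no filter, and for RS minus TwoRA 0.846 with a pseudocount of 1, 0.917 and 0.838. With an array left out, the tissue correlation of TwoRA with OneRA ranged from 0.929 (without kidney OneRA replicate 1) to 0.938, that of RS with TwoRA from 0.846 (without kidney RS 10 ng replicate 3) to 0.853, and the TwoRA minus OneRA effect from 0.746 (without kidney OneRA replicate 1) to 0.767.

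The median SD between replicate arrays moved with the treatment of dim probe sets. With a pseudocount of 1 it was 0.131 by OneRA, 0.157 by TwoRA and 0.219 by RS in the reference, and 0.199, 0.179 and 0.332 in kidney. At 100, 30 and 3 ng by RS it was 0.243, 0.218 and 0.322. With the larger pseudocount the reference values were 0.0924, 0.105 and 0.142, the kidney values 0.137, 0.118 and 0.209, and the RS input values 0.151, 0.136 and 0.202. With no filter the reference values were 0.151, 0.165 and 0.227, the kidney OneRA and TwoRA values 0.212 and 0.180, and RS at 100 and 30 ng 0.233 and 0.219. With a minimum signal of 500 the reference values were 0.0774, 0.0962 and 0.128, the kidney values 0.124, 0.111 and 0.227, and RS at 100, 30 and 3 ng 0.154, 0.117 and 0.193. Quantile normalization gave 0.124 for reference OneRA, 0.194 for RS at 100 ng and 0.172 at 30 ng.

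The mean 3′ to 5′ ratio depended on which transcripts were averaged. TwoRA minus OneRA in kidney was 1.09 without Gapdh, 1.74 without transferrin receptor and 0.89 without pyruvate carboxylase, and in the reference 0.43 without Gapdh. RS minus OneRA in kidney was 1.04 without transferrin receptor and 2.06 without pyruvate carboxylase. In the reference it was 0.72 without beta-actin, 0.16 without transferrin receptor and 1.79 without pyruvate carboxylase. RS minus TwoRA reversed without transferrin receptor, to -0.71 in kidney and -0.54 in the reference. In kidney it was 0.65 without Gapdh and 1.17 without pyruvate carboxylase, and in the reference 0.036 without beta-actin and 1.21 without pyruvate carboxylase. Signal over background limits the ratio for transferrin receptor, whose 5′ probe set was present on no RS array and on no reference TwoRA array. It limits that for pyruvate carboxylase too, whose 5′ probe set was present on 1 of 3 RS arrays at 10 ng in each RNA and on no reference TwoRA array, and whose 3′ probe set was present on no reference RS array. It also limits folds of genes not present in the dimmer group to lower bounds.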

Other observations

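The test of probe sets of the same gene in this part was chosen only after the result was seen.

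Many genes are measured by several probe sets, which lie along the same gene. Of 2645 genes with several called probe sets in RS minus OneRA in kidney, 1332 (50.4%) had calls in opposite directions, where independent directions would give 56.5%. In kidney minus reference by OneRA it was 24 of 1687 genes (1.42%), and in TwoRA minus OneRA in kidney 191 of 535 (35.7%). The difference of a gene's brightest probe set correlated with that of its next brightest at 0.195 for RS minus OneRA in kidney, 0.164 for TwoRA minus OneRA in kidney and 0.839 for kidney minus reference by OneRA, across 6218 genes, which are not independent replicates. The share of genes with opposite calls was 35.5 times higher between RS and OneRA in kidney than between kidney and reference by OneRA. Kidney minus reference by RS had a larger share, 63 of 1516 genes (4.16%), so the size of the ratio depends on the procedure it is set against. A hypothesis consistent with this is that the labelling procedure may act on parts of transcripts rather than on whole transcripts. The test cannot decide this, because anything peculiar to a probe set within a procedure cancels in kidney minus reference and does not cancel between procedures. It does not exclude that some probe sets of a gene measure another transcript, and it was made on the data that raised the hypothesis.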
